A study of Daphnia magna with 15 samples.

How the data were processed

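RNA was sequenced from pools of whole water fleas (Daphnia magna, clone P132.85) kept at 20 °C from hatch until the first clutch lay in the brood pouch. The 15 libraries form 5 diets with 3 libraries each: a green alga without EPA (eicosapentaenoic acid, a 20-carbon polyunsaturated fatty acid; GA), the same alga with EPA added in liposomes (GA+EPA), a cyanobacterium without EPA (CY), that cyanobacterium with EPA (CY+EPA), and the flagellate Cryptomonas, which contains EPA by itself (CRY). The labels give the number of animals per pool as 3 in the source name and 5 in the protocol, and this could not be settled from the files. No pool with empty liposomes is listed, so the EPA comparisons carry the liposomes with them. Libraries are named here by diet and by the number in their title (GA 1 to 3, GA+EPA 2 to 4, CY 1 to 3, CY+EPA 1 to 3, CRY 1, 2 and 5).

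The deposited library files give, per the file headers, an expected count, a TPM and an FPKM value for each of 26646 gene models. Expected counts are the authors' estimates of fragments per gene made with RSEM 1.2.31, per the submitters' processing notes, which also name Trimmomatic, Bowtie2 and edgeR without versions, roles or order. Between 11.79% and 13.54% of the genes in a library had a non-whole expected count, because RSEM divides fragments among similar genes. The deposited series table holds FPKM values (fragments per kilobase per 1e6 fragments, calculated by the authors); its largest difference from the FPKM columns of the library files was 0, so it carries no scaling between libraries. Genome build and annotation release are not given in the sources used here. The TPM columns were not analysed here.

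Gene descriptions came from the deposited annotation table: 10116 gene models had an informative product name, 3273 were described only by a hit to the arthropod orthologous groups (artNOG), and 13257 had neither. The table repeated 1 transcript number, and 1 gene model had no annotation line. None of the locus tags (0) occurred in the RefSeq table supplied, so genes are named by their APZ42 locus tag and deposited description. These names rest on sequence similarity, and no reference genome was at hand to place the genes further than the scaffold coordinates of the annotation table.

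Library totals ran from 18.18 to 23.81 (in 1e6) expected counts, and 18508 to 19104 genes had at least 1 count. Replicates differed far more than counting noise allows (chi-square per gene 4.66 in the closest pair of replicates, where 1 is counting noise alone), so precision was set by the spread between pools and not by depth. The p-values use 1 spread per gene, pooled over diets that differ in spread.

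Expected counts were rounded to whole numbers and analysed in R 4.3.3 with edgeR 4.0.16. Genes with too few counts were removed with filterByExpr over the 5 groups, which kept 15377 genes and removed 11269. Library sizes were scaled with TMM, and a quasi-likelihood model with 1 mean per diet was fitted to all 15 libraries (common biological coefficient of variation 0.273). Each comparison used the quasi-likelihood F test, and a gene was called when its Benjamini-Hochberg adjusted p was under 0.05. The 10 comparisons were GA+EPA vs GA, CY+EPA vs CY, their average over both foods, their difference (EPA effect, CY minus GA), CY vs GA, CY+EPA vs GA+EPA, and CRY against each other diet. Levels are given as counts per 1e6 (CPM), mean ± SD of 3 libraries; log2 fold changes are given ± their standard error from the fit.

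Gene lists for 30 functions were fixed before the data were examined, each as a text pattern applied to the deposited descriptions, and were tested with camera (limma 3.58.1) on log2 CPM at the preset inter-gene correlation of 0.01, with adjustment over the lists of a comparison. The same test was repeated with the correlation estimated for each list. The list for photosynthesis, meant to catch RNA of the food organisms, matched 0 genes. Letters of the COG functional classes were tested in the same way. Genes named in the text came from a rule fixed at the same time: in 5 comparisons (GA+EPA vs GA, CY+EPA vs CY, CY vs GA, CRY vs GA, CRY vs CY), called genes with an informative description, a mean of at least 1 CPM and no overlap between the libraries compared, taking the 6 largest changes in each direction and, from each list, the member with the smallest p in each direction. Where no gene passed, the 5 annotated genes with the smallest p were taken. Of unchanged genes, 10% separate 3 libraries from 3 others by chance. The rule returned more genes than could be described, and those described were picked after their values were seen, mainly as genes whose call stood when any library was left out. A few neighbours in function, stated where they appear, were also added after the values were seen.

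Correlations of fold changes for 3 pairs of comparisons without shared libraries have a jackknife standard error over libraries, which served as the spread when alternatives were judged. Those of comparisons with shared libraries have none and are given with the covariance beside simulated values. Overlaps of calls are given beside the number expected for independent lists and beside 10 simulations of unchanged groups that shared the same control libraries. Simulations from the fitted dispersions recovered 6% to 19.4% of 1.5-fold, 37.3% to 50.7% of 2-fold and 71.2% to 80.3% of 4-fold changes. Of 15137 unchanged genes 0 to 6 were called, and 0 of 29 random lists. Random lists lack the correlation within functional lists (estimated at 0.348 for cuticle proteins), so false list calls from it were not tested.

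Alternatives planned ahead were DESeq2 size factors in place of TMM, the DESeq2 1.42.0 Wald test, no count filter, only the groups compared in the fit, a replicate block, a block for library number (48563 to 48570 against 48580 to 48586), a 2-fold minimum, limma on log2(FPKM + 1), and the omission of each library in turn. Chosen after the data were seen were the omission of CRY 5 and CY 3 together, the omission of GA 2 and GA 3 together, the removal of the cuticle, chitin and collagen genes, and list members from product names only. Groups were also regrouped in every possible split of their libraries (10 splits for 3 against 3); for the averaged and the difference test, 100 combinations of splits were used, the real one and others drawn with a single random seed from all pairs of splits with the CY sides in either order. Bootstrap intervals of medians used 2000 resamples of genes at the 95% level. Tables and figures were made with Python 3.11.15 and matplotlib 3.10.9.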

Results

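Gene expression was measured in 15 libraries from pools of whole Daphnia magna of 1 clone, 3 libraries for each of 5 diets. The diets ask what EPA, a fatty acid used for eicosanoids and membranes, does to animals raised on foods that lack it. GA animals ate the green alga Acutodesmus obliquus and CY animals the cyanobacterium Synechococcus elongatus. GA+EPA and CY+EPA animals ate the same foods with EPA in liposomes, and CRY animals ate the flagellate Cryptomonas, a natural source of EPA. Totals of expected counts (in 1e6) were 21.31, 20.79 and 20.54 for GA 1, 2 and 3, and 23.21, 18.3 and 22.42 for GA+EPA 2, 3 and 4. They were 22.78, 21.89 and 20.28 for CY 1, 2 and 3, 19.94, 22.18 and 23.81 for CY+EPA 1, 2 and 3, and 19.06, 18.18 and 22.98 for CRY 1, 2 and 5.

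The libraries of CY+EPA lay closest together (correlation of log2 CPM between replicates 0.989 to 0.991). Those of GA (0.945 to 0.955) and GA+EPA (0.928 to 0.967) lay furthest apart, with CY from 0.967 to 0.987 and CRY from 0.958 to 0.984. On the principal components, GA+EPA 2 stood out on the axis with 36% of the variance (score 120.1). GA 2 (97.1) and GA 3 (55.7) stood out on the axis with 24%. The 100 most abundant genes held 32.22% to 41.92% of the counts, with the highest shares in CY 3 (41.92%) and CRY 5 (40.65%). CY 3, CRY 5 and CY+EPA 1 carry consecutive library numbers. CY 3 and CRY 5 deviated from their own groups in similar genes (r = 0.492 between their deviations). CRY 5 correlated alike with CY 3 (0.982) and CY+EPA (0.981 to 0.982). CY, CY+EPA, CRY 1 and CRY 5 come from a lower range of library numbers, and GA, GA+EPA and CRY 2 from a higher. Comparisons of GA with CY also compare these ranges.

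**Figure D1:**
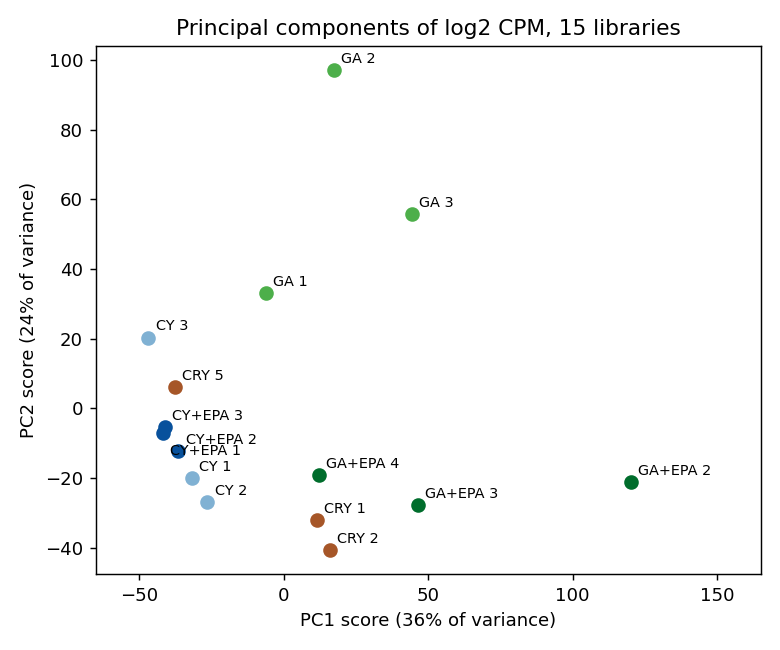
Principal component scores of the 15 libraries from log2 CPM of the tested genes, 1 point per library, coloured by diet (n = 3 per diet).

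EPA added to the green alga (GA+EPA vs GA) raised single genes named for sterol binding, iron storage and fatty acid breakdown and lowered visual opsins. A putative Niemann-Pick type C gene (APZ42_015058), whose relatives bind sterols in the gut and lysosome, rose from 208.2 ± 73.8 to 735.8 ± 322 CPM (mean ± SD, n = 3, log2 fold change 1.82 ± 0.34, adjusted p = 0.00909). Ferritin 1 heavy chain (APZ42_022329), an iron store, rose from 282.9 ± 108 to 843.2 ± 106 CPM (1.58 ± 0.24, adjusted p = 0.0033). An acyl-CoA dehydrogenase (APZ42_017127) rose from 101.7 ± 37.3 to 775.2 ± 465 CPM (2.93 ± 0.43, adjusted p = 0.003). The long-wavelength opsin APZ42_025535 fell from 1635 ± 66.3 to 1072 ± 117 CPM (−0.61 ± 0.09, adjusted p = 0.00316). Of 15377 genes tested, 582 rose and 540 fell.

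Among genes of fatty acid and eicosanoid metabolism, leukotriene A-4 hydrolase (APZ42_022054) rose from 66.86 ± 28.9 to 193.9 ± 13.5 CPM (1.54 ± 0.24, adjusted p = 0.00423). This enzyme of the mammalian eicosanoid route thereby reached its level on the cyanobacterium (193.8 ± 13.1). Of 24 eicosanoid genes 3 rose, 2 fell and 19 were not called (4 and 2 adjusted over the list alone). Of 16 desaturases and elongases 1 rose, 5 fell and 10 were not called (2 and 7 adjusted over the list alone, camera adjusted p = 0.0586). Stearoyl-CoA desaturase 5 (APZ42_016545) fell from 63.87 ± 11.4 to 35.85 ± 7.78 CPM (−0.83 ± 0.18, adjusted p = 0.0153). The elongase 1 homologue (APZ42_011361) fell from 5.278 ± 2.96 to 0.3979 ± 0.195 CPM (−3.70 ± 0.50, adjusted p = 0.00181). Elongase 6 (APZ42_018283), which lengthens 16-carbon chains in mammals, rose from 121.7 ± 9.35 to 187.9 ± 30.5 CPM (0.63 ± 0.15, adjusted p = 0.0241), but not without GA 1, GA 2 or GA+EPA 2. No list call was made for fatty acid synthesis (10 genes, 0 rose and 1 fell, 0 and 2 adjusted over the list alone) or beta-oxidation (29, 2 and 0, 2 and 0, adjusted p = 0.189). Lipases (42, 3 and 1, 3 and 1) and lipid transport (37, 0 and 6, 2 and 8) were not called as lists either.

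The sterol list rose, with 4 of 24 genes higher, 0 lower and 20 not called (6 and 0 adjusted over the list alone). Its camera test gave adjusted p = 0.0265, and adjusted p = 0.321 with an estimated correlation. Niemann-Pick C1 (APZ42_023212, 0.63 ± 0.15, adjusted p = 0.0228) was called, as was Delta(24)-sterol reductase (APZ42_023089, from 120.8 ± 11.5 to 201.6 ± 18.9 CPM), looked at after the values were seen. Each of these calls ended in 4 of 6 omissions of a library. Of 22 genes for iron storage and haemoglobins 3 rose and 0 fell (3 and 0 adjusted over the list alone), and the list was not called (adjusted p = 0.862). The metal transporter NRAMP2 (APZ42_029718), also looked at afterwards, rose from 35.84 ± 5.43 to 72.56 ± 5.94 CPM (1.02 ± 0.18, adjusted p = 0.00746). Other genes of this kind fell, a ferric-chelate reductase (APZ42_011064, −5.18, adjusted p = 0.0154) and a transferrin (APZ42_015262, −0.96, adjusted p = 0.0398), while a reductase homologue (APZ42_021657, 1.16, adjusted p = 0.0151) rose. The ferritin genes APZ42_022329 and APZ42_022342 are neighbours and similar, so reads may be shared between them and their separate values are uncertain.

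Digestive enzymes changed in both directions. Zinc carboxypeptidase A1 (APZ42_000512) rose from 23.1 ± 6.96 to 78.69 ± 5.21 CPM (1.77 ± 0.20, adjusted p = 0.000835), and a trypsin (APZ42_031107) rose from 23.25 ± 8.37 to 70.67 ± 12.1 CPM (1.60 ± 0.23, adjusted p = 0.00258). Trypsin-7 (APZ42_013587) fell from 594.4 ± 105 to 277.2 ± 6.74 CPM (−1.10 ± 0.12, adjusted p = 0.000835). Of 37 serine proteases 8 rose and 6 fell (10 and 10 adjusted over the list alone), and of 84 other peptidases 21 rose and 4 fell (24 and 21). Carbohydrate digestion rose, with 10 of 58 genes higher and 3 lower (15 and 4 adjusted over the list alone). Its test gave adjusted p = 0.0153, and adjusted p = 0.79 with an estimated correlation. Lysosomal alpha-glucosidase (APZ42_021394) rose by 1.18 ± 0.13 (adjusted p = 0.000835), and an endo-beta-1,4-mannanase (APZ42_011768) fell by 2.22 ± 0.31 (adjusted p = 0.00209).

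Opsins and phototransduction fell, with 0 of 45 genes higher, 11 lower and 34 not called (1 and 12 adjusted over the list alone). The list had adjusted p = 0.0153, and adjusted p = 0.639 with an estimated correlation. All 11 called genes were opsins. The long-wavelength opsin APZ42_025431 fell from 497.9 ± 33.7 to 322.2 ± 40.5 CPM (−0.63 ± 0.10, adjusted p = 0.00376), and held 225.8 ± 9.29 CPM on CY and 225.6 ± 15.3 on CRY. Opsin genes occur in clusters of close copies here, so reads may be shared among them. Neurotransmission fell, with 1 of 69 genes higher and 2 lower (1 and 2 adjusted over the list alone), at adjusted p = 0.0265, and adjusted p = 0.639 with an estimated correlation.

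Cuticle proteins rose as a list, with 6 of 148 genes higher, 7 lower and 135 not called (31 and 14 adjusted over the list alone). The list had adjusted p = 0.0153, and adjusted p = 0.924 with an estimated correlation. Without GA 1 or GA+EPA 2 it turned to the other direction (adjusted p = 0.911 and 0.913). Of 74 collagens and matrix genes 4 rose and 11 fell (6 and 17 adjusted over the list alone), and of 50 chitin genes 4 rose and 4 fell (7 and 8). A collagen (APZ42_029452) held 3.844, 193.1 and 56.05 CPM in GA 1, 2 and 3 against 0.6225 ± 0.464 in GA+EPA (−7.05 ± 1.28, adjusted p = 0.00774). A cuticular protein (APZ42_023132) held 0.4133, 15.01 and 54.37 CPM against 0.1971 ± 0.104 (−6.82 ± 1.28, adjusted p = 0.00904). Elongase 5 (APZ42_024104) held 2.025, 63.92 and 77.32 CPM against 0.4313 ± 0.245 (−6.76 ± 1.11, adjusted p = 0.0047). GA 2 and GA 3 were thus high and GA 1 low in these genes.

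**Figure D2:**
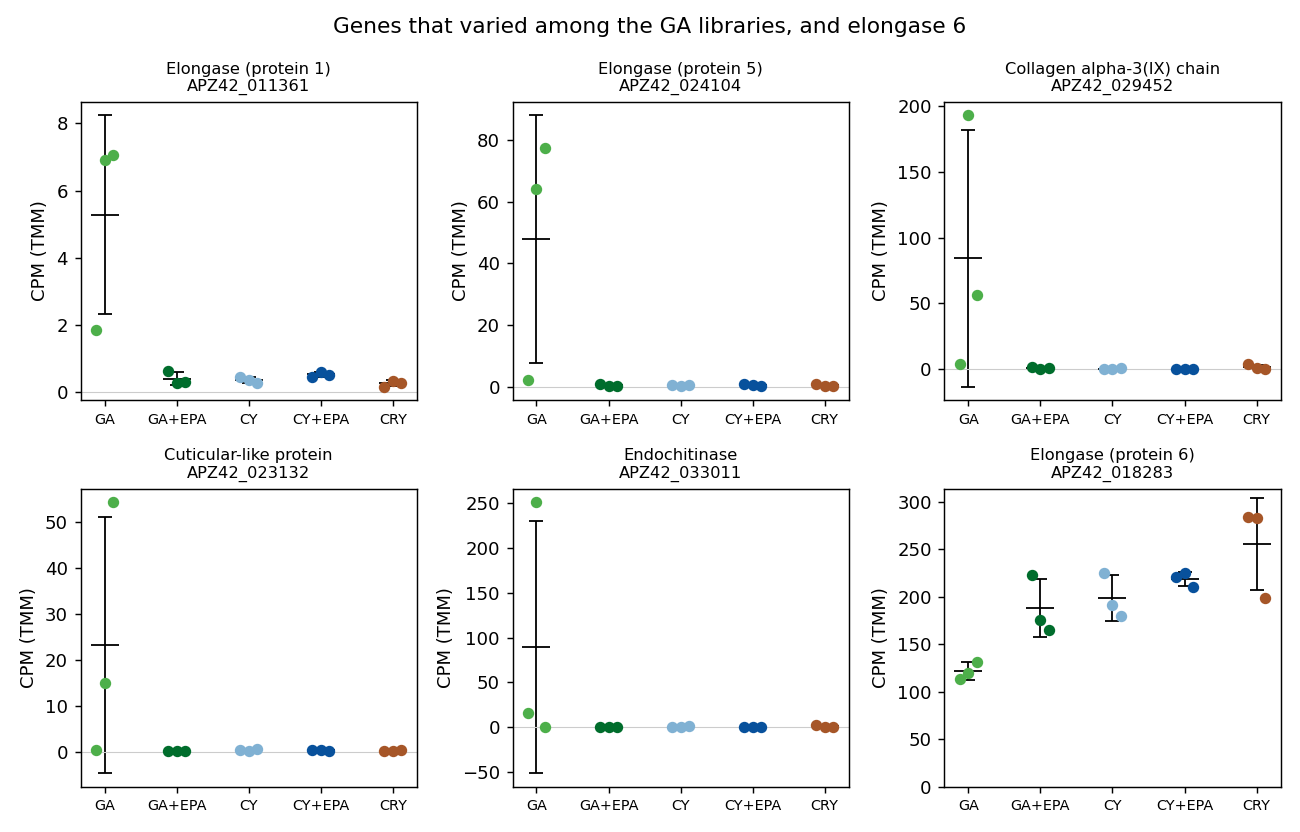
Genes that varied among the GA libraries: elongase 1, elongase 5, a collagen, a cuticular protein, an endochitinase and elongase 6. Each panel shows the CPM of 3 libraries per diet, left to right in the order of their title numbers, with mean and SD.

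The mitochondrial respiratory chain was called upward with 0 of 81 genes called (0 and 0 adjusted over the list alone), at adjusted p = 0.0142, and adjusted p = 0.79 with an estimated correlation. Its median log2 fold change was 0.05. Of 25 genes of hormone signalling 7 rose and 2 fell (11 and 5 adjusted over the list alone). A juvenile hormone binding protein (APZ42_028755) rose by 1.49 ± 0.19 (adjusted p = 0.00167), and the nuclear receptor HR3 (APZ42_023433) fell by 3.41 ± 0.60. Of 45 cytochromes P450 5 rose and 4 fell (7 and 7 adjusted over the list alone). Of 135 genes for conjugation and efflux 4 rose and 4 fell (3 and 4). Immunity had 3 rising and 3 falling of 35 (5 and 5), embryo markers 3 and 3 of 75 (4 and 4), and yolk proteins 1 and 1 of 40 (0 and 0). Antioxidant enzymes had 1 and 1 of 46 (0 and 1), muscle 1 and 1 of 55 (0 and 0), heat shock proteins 1 and 0 of 31 (1 and 0), and DNA replication 0 and 1 of 87 (0 and 1). Ribosomal proteins (173) and transposable elements (19) had 0 called genes.

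The number of genes called in GA+EPA vs GA depended on the libraries and on how their spread was estimated. It was 1122 as fitted, 598 without GA 2, 679 without GA+EPA 2, 235 without both GA 2 and GA 3, and 0 when only these 6 libraries were fitted. A 2-fold minimum left 703, and the DESeq2 Wald test called 1792. With limma on FPKM 29.5% of the calls were higher in place of 51.9%, where the median of all genes shifted by −0.121. Without GA 2 and GA 3, the calls of the Niemann-Pick type C gene (1.56), the acyl-CoA dehydrogenase APZ42_017127 (2.67), opsin APZ42_025535 (−0.60) and elongase 1 (−2.20) ended. Those of ferritin 1, leukotriene A-4 hydrolase, zinc carboxypeptidase A1, trypsin-7, lysosomal alpha-glucosidase and stearoyl-CoA desaturase 5 stood. A UDP-glucuronosyltransferase (APZ42_030894, −4.34 ± 1.03) turned to 0.19 in that fit.

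EPA added to the cyanobacterium (CY+EPA vs CY) changed no gene past the threshold. Among genes that were not called (adjusted p = 1), trypsin-7 APZ42_020188 stood at 4.212 ± 0.477 CPM on CY and 6.849 ± 0.936 on CY+EPA (0.70 ± 0.14). Neutral alpha-glucosidase AB (APZ42_019360) stood at 20.98 ± 3.3 and 10.41 ± 0.245 CPM (−1.01 ± 0.23). The Niemann-Pick type C gene stood at 24.52 ± 5.55 CPM on CY and 53.77 ± 9.91 on CY+EPA (1.13 ± 0.34, adjusted p = 1). The acyl-CoA dehydrogenase APZ42_017127 stood at 49.51 ± 12.8 and 134.7 ± 13 CPM (1.44 ± 0.41, adjusted p = 1). Leukotriene A-4 hydrolase (0.04 ± 0.24), ferritin 1 (0.01 ± 0.23) and zinc carboxypeptidase A1 (0.00 ± 0.19) stayed level. edgeR called 0 genes, DESeq2 1 and limma 0, and edgeR also called 0 with only these groups fitted. Of 15377 genes 412 had an unadjusted p under 0.05. That is a share under 0.05, fewer than unchanged genes alone would be expected to give. No list was called, the lowest adjusted p being 0.0818 for ribosomal proteins. Of the COG classes, translation (J) was called upward at adjusted p = 0.0344, and adjusted p = 0.859 with an estimated correlation. It was also called upward in CY vs GA (4.3e-05), CY+EPA vs GA+EPA (4.02e-07), CRY vs GA (0.00558) and CRY vs GA+EPA (0.000876), and downward in CRY vs CY+EPA (0.00174). Classes A, B, C or F were called in some of these, and no class call stood with an estimated correlation. Adjusted over the list alone, 2 serine proteases rose and 1 gene of carbohydrate digestion fell. In data simulated for CY+EPA vs CY 44.8% of 2-fold and 19.4% of 1.5-fold changes were found, so many changes of that size would be missed.

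Averaged over both foods, EPA raised the acyl-CoA dehydrogenase APZ42_017127 (2.19 ± 0.30, adjusted p = 0.0113), a call that stood in all 12 omissions of a library. The Niemann-Pick type C gene rose as well (1.48 ± 0.24, adjusted p = 0.0174), but not without CY 3 or any library of CY+EPA. The blue opsin APZ42_011413 (−0.45 ± 0.07, adjusted p = 0.0167) and the long-wavelength opsin APZ42_025431 (−0.41 ± 0.07, adjusted p = 0.0193) fell. Of 15377 genes 106 rose and 65 fell. Of 45 opsin and phototransduction genes 0 were higher and 9 lower (0 and 12 adjusted over the list alone). The list was called downward at adjusted p = 0.0423 (0.706 with an estimated correlation), though its median log2 fold change was 0.049. Neurotransmission fell (0 and 1 of 69, 0 and 2) at adjusted p = 0.0418 (0.691 with an estimated correlation). The sterol list rose (1 and 0 of 24, 3 and 0 adjusted over the list alone) at adjusted p = 0.0423, and adjusted p = 0.371 with an estimated correlation. Carbohydrate digestion (2 and 1 of 58, 5 and 2 adjusted over the list alone) and cuticle proteins (0 and 0 of 148, 0 and 0) were called upward, each at adjusted p = 0.0423, and adjusted p = 0.904 with an estimated correlation. The cuticle list turned direction without GA 1 (adjusted p = 0.711) or GA+EPA 2 (0.888).

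The averaged count of 171 depended on nearly every library. It was 192 and 118 without GA 2 and GA+EPA 2, 276, 326 and 274 without GA 1, GA 3 and GA+EPA 4, and 82 without GA+EPA 3. It fell to 51, 85 and 15 without CY 1, CY 2 and CY 3, and to 17, 11 and 14 without CY+EPA 1, 2 and 3. It was 16 without CRY 5 and CY 3, 90 without GA 2 and GA 3, 93 with only the groups compared, 49 with a 2-fold minimum and 801 with DESeq2. The share of higher genes, 62% as fitted, was 39.7% with limma on FPKM, 43.8% and 37.4% without GA 1 and GA 3, and 43.1% and 26.7% without CY 1 and CY 3. It was 29.4%, 18.2% and 42.9% without CY+EPA 1, 2 and 3, so the balance of directions is not settled.

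The effect of EPA differed between the foods in 90 genes by the interaction test (EPA effect, CY minus GA, 32 positive and 58 negative). Trypsin-7 APZ42_020188 fell with EPA on the alga (−0.87 ± 0.15, adjusted p = 0.00521) and stood at 0.70 ± 0.14 on the cyanobacterium. Its difference of 1.57 ± 0.20 (adjusted p = 0.0109) held in all but 1 of 12 omissions. Zinc carboxypeptidase A1 rose by 1.77 on the alga and stood at 0.00 on the cyanobacterium (difference −1.77 ± 0.27, adjusted p = 0.0256). For ferritin 1 (−1.57 ± 0.33, adjusted p = 0.06), leukotriene A-4 hydrolase (−1.49 ± 0.34, adjusted p = 0.0748) and the Niemann-Pick type C gene (−0.69 ± 0.47, adjusted p = 0.616) no difference passed the threshold.

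By list, other peptidases differed downward (1 and 9 of 84, 5 and 21 adjusted over the list alone) at adjusted p = 0.0192, and adjusted p = 0.835 with an estimated correlation. So did carbohydrate digestion (1 and 3 of 58, 3 and 14) at adjusted p = 0.0192 (0.781 with an estimated correlation). Cuticle proteins (0 and 0 of 148, 0 and 0) were called downward at adjusted p = 0.0192 (0.835 with an estimated correlation). The respiratory chain (0 and 0 of 81, 0 and 0) was called downward at adjusted p = 0.000644, and adjusted p = 0.781 with an estimated correlation. Desaturases and elongases differed upward (1 and 0 of 16, 6 and 0) at adjusted p = 0.031 (0.781 with an estimated correlation). Opsins (0 and 0 of 45, 2 and 0) were called upward at adjusted p = 0.0192 (0.781 with an estimated correlation). Ribosomal proteins (0 and 0 of 173, 0 and 0) had adjusted p = 0.0192 upward, and adjusted p = 0.835 with an estimated correlation. Without GA 1 (0.878) or GA+EPA 2 (0.928) the cuticle list turned direction.

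The interaction count of 90 moved by more than 1.5 times with every library omitted. It was 211, 138 and 204 without GA 1, 2 and 3, and 48, 34 and 191 without GA+EPA 2, 3 and 4. It fell to 7, 2 and 10 without CY 1, 2 and 3, and to 7, 7 and 12 without CY+EPA 1, 2 and 3. DESeq2 called 607, and 35 remained with only the groups compared. With limma on FPKM 59.2% of the calls were positive in place of 35.6%, where the median of all genes shifted by 0.133.

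Between the foods without EPA (CY vs GA), which also differ in the range of library numbers, single genes for digestive enzymes, an oxygen-binding globin and opsins differed. Chymotrypsin-C (APZ42_018880) rose 67-fold, from 10.23 ± 3.52 to 685.5 ± 54.6 CPM (6.07 ± 0.43, adjusted p = 1.95e-05), and a carboxylic ester hydrolase (APZ42_031919) from 1.46 ± 0.313 to 142.1 ± 43 CPM (6.60 ± 0.66, adjusted p = 0.000137). Cytoglobin-2 (APZ42_028671) rose from 19.03 ± 1.65 to 72.46 ± 2.66 CPM (1.93 ± 0.31, adjusted p = 0.00304). By contrast, Niemann-Pick type C fell from 208.2 ± 73.8 to 24.52 ± 5.55 CPM (−3.09 ± 0.36, adjusted p = 0.000402). The blue opsin APZ42_011413 fell from 50.18 ± 3.59 to 21.95 ± 1.26 CPM (−1.19 ± 0.10, adjusted p = 5.48e-05). Of 15377 genes 819 rose and 988 fell.

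Other peptidases rose, with 26 of 84 genes higher and 5 lower (32 and 8 adjusted over the list alone), at adjusted p = 8.33e-05, and adjusted p = 0.467 with an estimated correlation. Aminopeptidase N (APZ42_014896) rose from 3.71 ± 0.653 to 20.63 ± 2.3 CPM (2.47 ± 0.21, adjusted p = 5.48e-05). Carbohydrate digestion rose (17 and 5 of 58, 21 and 7) at adjusted p = 0.00364 (0.467 with an estimated correlation). Lipases rose (9 and 1 of 42, 11 and 3) at adjusted p = 0.0454 (0.467 with an estimated correlation). With DESeq2 size factors the lipase list was not called (adjusted p = 0.05). A pancreatic lipase-related gene (APZ42_032860) rose from 43.97 ± 7.48 to 166.3 ± 26.7 CPM (1.92 ± 0.19, adjusted p = 0.000137). Of 37 serine proteases 7 rose and 3 fell (9 and 7 adjusted over the list alone), without a list call.

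Haemoglobins and iron storage rose on CY, with 12 of 22 genes higher and 0 lower (13 and 0 adjusted over the list alone), at adjusted p = 5.03e-05, and adjusted p = 0.29 with an estimated correlation. The haemoglobin APZ42_022505 rose from 1376 ± 192 to 4012 ± 300 CPM (1.54 ± 0.32, adjusted p = 0.01). The globin APZ42_022503 rose from 3936 ± 303 to 8934 ± 343 CPM (1.18 ± 0.27, adjusted p = 0.0152), but not without CY 2. These globins are neighbours and may share reads. The respiratory chain rose (13 and 1 of 81, 19 and 1) at adjusted p = 2.65e-07 (0.467 with an estimated correlation). Ribosomal proteins rose (9 and 2 of 173, 5 and 2) at adjusted p = 6.11e-08 (0.467 with an estimated correlation). An example is l7ae (APZ42_024866, 1.17 ± 0.20). DNA replication rose (11 and 2 of 87, 11 and 2) at adjusted p = 0.0342 (0.579 with an estimated correlation). PCNA (APZ42_018111) rose by 0.87 ± 0.14. Yolk proteins (1 and 3 of 40, 0 and 0) were called upward at adjusted p = 0.00126 (0.467 with an estimated correlation). Antioxidant enzymes (2 and 2 of 46, 0 and 1) were called upward at adjusted p = 0.00845, and adjusted p = 0.467 with an estimated correlation.

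Cuticle proteins fell on CY, with 0 of 148 genes higher and 19 lower (0 and 44 adjusted over the list alone), at adjusted p = 6.12e-05, and adjusted p = 0.579 with an estimated correlation. Without GA 3 the cuticle list was not called (adjusted p = 0.0545), nor without both GA 2 and GA 3 (adjusted p = 0.941). Chitin metabolism fell (1 and 7 of 50, 1 and 9 adjusted over the list alone) at adjusted p = 0.0223, and adjusted p = 0.29 with an estimated correlation. Opsins fell (0 and 13 of 45, 0 and 15 adjusted over the list alone) at adjusted p = 3.82e-09, and adjusted p = 0.103 with an estimated correlation. The 13 were 11 opsins and 2 beta-arrestins. Neurotransmission fell (0 and 7 of 69, 0 and 6 adjusted over the list alone) at adjusted p = 0.00314, and adjusted p = 0.29 with an estimated correlation. Muscle fell (0 and 3 of 55, 0 and 2) at adjusted p = 0.0102, and adjusted p = 0.579 with an estimated correlation. In lipid metabolism, sterol regulatory element-binding protein 1 (APZ42_013351, 0.84 ± 0.16) and a group 3 secretory phospholipase A2 (APZ42_017524, 1.40 ± 0.20, adjusted p = 0.00147) rose. ATP-citrate synthase (APZ42_020279, −0.90 ± 0.17) fell. Beta-oxidation (1 and 6 of 29, 3 and 7 adjusted over the list alone), lipid transport (7 and 8 of 37, 8 and 11) and desaturases and elongases (1 and 5 of 16, 1 and 5) had no list call.

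The count of 1807 for CY vs GA was 894 without GA 2, 750 without CY 1, 752 without CY 2 and 395 without both GA 2 and GA 3. It was 1068 with only these groups, 725 with a 2-fold minimum and 47 with a block for the library number. Chymotrypsin-C, aminopeptidase N, the ester hydrolase APZ42_031919, cytoglobin-2, ribosomal protein l7ae and the blue opsin kept their calls with that block. Niemann-Pick type C, the pancreatic lipase-related gene, PCNA, sterol regulatory element-binding protein 1, the phospholipase A2 and ATP-citrate synthase lost them. With limma on FPKM 2880 genes were called, 12.3% of them higher in place of 45.3%, where the median of all genes shifted by −0.152.

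With EPA present in both foods (CY+EPA vs GA+EPA) chymotrypsin-C and aminopeptidase N were higher on the cyanobacterium again. Chymotrypsin-C rose from 49.19 ± 15.2 to 439.3 ± 68.1 CPM (3.16 ± 0.37, adjusted p = 0.000668) and aminopeptidase N from 3.825 ± 0.349 to 19.04 ± 2.99 CPM (2.31 ± 0.21, adjusted p = 0.000263). Haemoglobin APZ42_022505 rose from 1258 ± 763 to 4607 ± 567 CPM (1.87 ± 0.32, adjusted p = 0.00577). The Niemann-Pick type C gene fell from 735.8 ± 322 to 53.77 ± 9.91 CPM (−3.77 ± 0.37, adjusted p = 0.000319). Of 15377 genes 1095 rose and 1455 fell.

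Cuticle proteins fell on CY+EPA, with 1 of 148 genes higher, 84 lower and 63 not called (7 and 102 adjusted over the list alone), at adjusted p = 5.69e-10, and adjusted p = 0.608 with an estimated correlation. Ribosomal proteins rose (60 and 2 of 173, 86 and 2 adjusted over the list alone) at adjusted p = 7.8e-14, and adjusted p = 0.482 with an estimated correlation. Haemoglobins and iron storage rose (11 and 0 of 22, 11 and 0 adjusted over the list alone) at adjusted p = 0.000753, and adjusted p = 0.428 with an estimated correlation. Serine proteases rose (7 and 3 of 37, 9 and 3 adjusted over the list alone) at adjusted p = 0.048, and adjusted p = 0.581 with an estimated correlation. The digestive lists called in CY vs GA were not called here, other peptidases (11 and 7 of 84, 12 and 7 adjusted over the list alone) at adjusted p = 0.31, carbohydrate digestion (5 and 2 of 58, 4 and 2) at 0.566 and lipases (3 and 3 of 42, 3 and 3) at 0.213. Yolk proteins (0 and 2 of 40, 0 and 1) were called upward at adjusted p = 0.0249, and adjusted p = 0.608 with an estimated correlation. Opsins fell (0 and 13 of 45, 0 and 14 adjusted over the list alone) at adjusted p = 3.46e-05, and adjusted p = 0.428 with an estimated correlation, with APZ42_025431 down by 0.70 ± 0.10. Muscle fell (0 and 5 of 55, 0 and 3) at adjusted p = 0.00791, and adjusted p = 0.619 with an estimated correlation. The count of 2550 was 834 without GA+EPA 2, and 689, 831 and 612 without CY+EPA 1, 2 and 3. It was 1138 with only these groups, 956 with a 2-fold minimum and 2 with a block for the library number.

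On the flagellate (CRY vs GA), which changes food as well as EPA, some ferritins and a sterol-binding gene were higher and opsins lower. Ferritin APZ42_022342 (1.53, adjusted p = 0.00812) and opsins changed likewise on EPA-free CY against GA. Ferritin APZ42_022342 rose 13.6-fold, from 18.93 ± 8.77 to 256.8 ± 47 CPM (3.76 ± 0.33, adjusted p = 6.04e-05), and the Niemann-Pick type C gene from 208.2 ± 73.8 to 1670 ± 383 CPM (3.00 ± 0.36, adjusted p = 0.000388). An endoribonuclease-like gene (APZ42_001739) rose from 646.8 ± 191 to 15740 ± 5060 CPM (4.60 ± 0.37, adjusted p = 4.2e-05). Opsin APZ42_025431 fell from 497.9 ± 33.7 to 225.6 ± 15.3 CPM (−1.14 ± 0.10, adjusted p = 5.32e-05). The acyl-CoA dehydrogenase APZ42_017127, raised by added EPA, fell from 101.7 ± 37.3 to 18.09 ± 4.53 CPM (−2.49 ± 0.43, adjusted p = 0.00399). Of 15377 genes 731 rose and 701 fell.

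**Figure D3:**
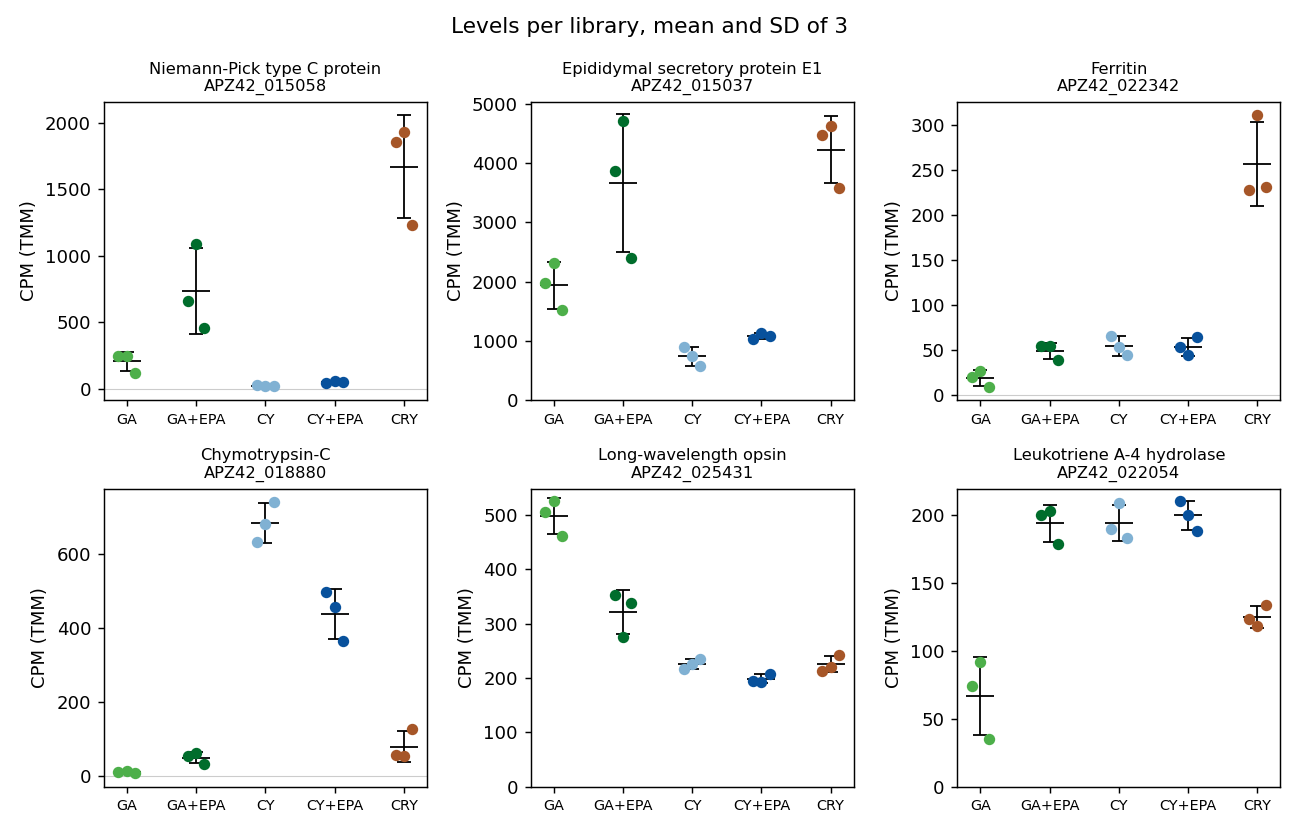
Genes that separated the diets: Niemann-Pick type C, epididymal secretory protein E1, ferritin APZ42_022342, chymotrypsin-C, opsin APZ42_025431 and leukotriene A-4 hydrolase. Each panel shows the CPM of 3 libraries per diet, left to right in the order of their title numbers, with mean and SD.

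Iron storage and haemoglobins rose on CRY, with 6 of 22 genes higher and 0 lower (6 and 0 adjusted over the list alone), at adjusted p = 1.17e-06, and adjusted p = 0.114 with an estimated correlation. Ferritin 1 (2.19 ± 0.24, adjusted p = 0.000247), ferritin APZ42_029162 (18.92 ± 2.86 to 97.44 ± 24.5 CPM, 2.36 ± 0.23, adjusted p = 0.00013) and cytoglobin-2 (2.65 ± 0.32) rose. Among genes looked at afterwards, NRAMP2 (2.07 ± 0.19, adjusted p = 7.24e-05) and ferric-chelate reductase 1 (APZ42_021650, 2.11 ± 0.27, adjusted p = 0.000698) rose as well, while ferric-chelate reductase APZ42_011064 (−4.55, adjusted p = 0.0194) and transferrin APZ42_015262 (−0.92, adjusted p = 0.0405) fell. The homologue APZ42_021657 rose by 1.37 (adjusted p = 0.0047). Sterol genes rose (7 and 0 of 24, 9 and 0) at adjusted p = 0.00272 (0.0888 with an estimated correlation). Yolk proteins rose (6 and 1 of 40, 9 and 3) at adjusted p = 4.16e-05 (0.262 with an estimated correlation). Hormone signalling rose (8 and 2 of 25, 10 and 5) at adjusted p = 0.0465 (0.437 with an estimated correlation). With DESeq2 size factors it was not called (adjusted p = 0.0506), and with members from product names only it turned direction (adjusted p = 0.881).

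In lipid metabolism, beta-oxidation fell on CRY (0 and 6 of 29, 0 and 8 adjusted over the list alone) at adjusted p = 0.0212, and adjusted p = 0.298 with an estimated correlation. Secretory phospholipase A2 (APZ42_017524) rose from 17.88 ± 1.51 to 76.15 ± 12.3 CPM (2.09 ± 0.21, adjusted p = 0.000125). Elongase 6 rose from 121.7 ± 9.35 to 255.5 ± 48.8 CPM (1.07 ± 0.15, adjusted p = 0.00114). Elongase 1 fell by 4.30 ± 0.53 (adjusted p = 0.000494) and elongase 5 by 6.73 ± 1.11 (adjusted p = 0.00319), both highest in GA 2 and GA 3. Eicosanoid genes had 7 higher and 1 lower of 24 (7 and 3 adjusted over the list alone) and lipid transport 5 and 5 of 37 (7 and 11), without a list call.

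Serine proteases rose on CRY (8 and 2 of 37, 10 and 4 adjusted over the list alone) at adjusted p = 0.0405, and adjusted p = 0.426 with an estimated correlation, among them chymotrypsin-C (2.95 ± 0.37, adjusted p = 0.000572). Other peptidases rose (20 and 4 of 84, 24 and 8 adjusted over the list alone) at adjusted p = 0.0344, and adjusted p = 0.579 with an estimated correlation. Conjugation and efflux rose (13 and 7 of 135, 18 and 8 adjusted over the list alone) at adjusted p = 0.0325, and adjusted p = 0.298 with an estimated correlation. The respiratory chain rose (9 and 1 of 81, 11 and 1) at adjusted p = 4.16e-05, and adjusted p = 0.426 with an estimated correlation. Ribosomal proteins rose (5 and 1 of 173, 0 and 0) at adjusted p = 0.00369, and adjusted p = 0.579 with an estimated correlation. Opsins fell (0 and 13 of 45, 3 and 13 adjusted over the list alone) at adjusted p = 4.16e-05, and adjusted p = 0.221 with an estimated correlation. Neurotransmission fell (0 and 5 of 69, 0 and 5) at adjusted p = 0.00439, and adjusted p = 0.262 with an estimated correlation. Muscle fell (0 and 1 of 55, 0 and 0) at adjusted p = 0.00439, and adjusted p = 0.437 with an estimated correlation. Cuticle proteins fell (2 and 8 of 148, 4 and 21 adjusted over the list alone) at adjusted p = 0.0325, and adjusted p = 0.666 with an estimated correlation. Without GA 2 and GA 3 the cuticle list turned direction (adjusted p = 0.1), and so did an NADH-ubiquinone oxidoreductase subunit (APZ42_020452, −2.59 ± 0.62 to 0.13).

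The count of 1432 for CRY vs GA was 808 without GA 2, 664 without CRY 1, 608 without CRY 2, 2257 without CRY 5 and CY 3, and 270 without GA 2 and GA 3. It was 355 with only these groups, 673 with a 2-fold minimum and 372 with a block for the library number. With limma on FPKM it was 2968, with 13.4% of the calls higher in place of 51% and a shift of the median by −0.177.

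In CRY vs CY, which changes food as well as EPA, sterol handling stood out. Niemann-Pick type C was 68.1-fold higher, at 1670 ± 383 against 24.52 ± 5.55 CPM (6.09 ± 0.41, adjusted p = 1.36e-05). Epididymal secretory protein E1 (APZ42_015037), a Niemann-Pick C2 type name on the same scaffold, rose from 743.7 ± 160 to 4225 ± 563 CPM (2.51 ± 0.25, adjusted p = 0.000355). Ferritin APZ42_022342 rose from 54.71 ± 10.8 to 256.8 ± 47 CPM (2.23 ± 0.31, adjusted p = 0.00427). Chymotrypsin-C fell from 685.5 ± 54.6 to 79.06 ± 42.4 CPM (−3.12 ± 0.37, adjusted p = 0.00137) and the pancreatic lipase-related gene from 166.3 ± 26.7 to 60.06 ± 9.14 CPM (−1.47 ± 0.19, adjusted p = 0.00303). Of 15377 genes 93 rose and 28 fell.

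The sterol list rose over CY, with 5 of 24 genes higher, 0 lower and 19 not called (6 and 0 adjusted over the list alone, adjusted p = 0.000137). Its call stood with an estimated correlation (adjusted p = 0.0139). Of the iron genes looked at afterwards NRAMP2 rose by 2.38 ± 0.19 (adjusted p = 5.85e-05) and ferric-chelate reductase 1 by 2.29 ± 0.28 (adjusted p = 0.00153). Haemoglobins and iron storage had 2 higher and 0 lower of 22 (6 and 1 adjusted over the list alone), without a list call. Other peptidases fell (2 and 4 of 84, 4 and 8 adjusted over the list alone) at adjusted p = 0.0188, and adjusted p = 0.679 with an estimated correlation. Cuticle proteins (0 and 0 of 148, 0 and 0 adjusted over the list alone) were called upward at adjusted p = 0.0316, and adjusted p = 0.814 with an estimated correlation. Ribosomal proteins (0 and 0 of 173, 0 and 0) were called downward at adjusted p = 0.00359, and adjusted p = 0.679 with an estimated correlation. Carbohydrate digestion had 1 higher and 5 lower of 58 (4 and 9 adjusted over the list alone).

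The count of 121 for CRY vs CY was 561 without CRY 5, 49 without CRY 1 or CRY 2, and 67, 59 and 60 without CY 1, CY 2 and CY 3. It was 410 with DESeq2, 72 with a 2-fold minimum and 47 with a block for the library number. Chymotrypsin-C stood at 55.47, 53.65 and 128.1 CPM in CRY 1, 2 and 5, so CRY 5 was the nearest of them to CY.

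The flagellate and the alga with added EPA (CRY vs GA+EPA) differ in the food as well as in the source of EPA. The endoribonuclease-like gene rose from 1818 ± 678 to 15740 ± 5060 CPM (3.11 ± 0.35, adjusted p = 0.00066). Ferritin APZ42_022342 rose from 49.38 ± 8.9 to 256.8 ± 47 CPM (2.38 ± 0.31, adjusted p = 0.00186) and ferritin APZ42_029162 from 21.91 ± 3.61 to 97.44 ± 24.5 CPM (2.15 ± 0.23, adjusted p = 0.000576). The acyl-CoA dehydrogenase APZ42_017127 fell from 775.2 ± 465 to 18.09 ± 4.53 CPM (−5.42 ± 0.49, adjusted p = 0.000359). The Niemann-Pick type C gene was not called (1.18 ± 0.34, adjusted p = 0.0834). Of 15377 genes 199 rose and 226 fell.

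Haemoglobins and iron storage rose over GA+EPA, with 5 of 22 genes higher, 0 lower and 17 not called (15 and 0 adjusted over the list alone, adjusted p = 3.42e-11). That call stood with an estimated correlation (adjusted p = 0.0462). Beta-oxidation fell (0 and 7 of 29, 1 and 9 adjusted over the list alone) at adjusted p = 5.31e-05, and adjusted p = 0.119 with an estimated correlation. Cuticle proteins fell (0 and 5 of 148, 1 and 64 adjusted over the list alone) at adjusted p = 5.49e-09, and adjusted p = 0.488 with an estimated correlation. Opsins fell (0 and 7 of 45, 0 and 7) at adjusted p = 0.00121, and adjusted p = 0.304 with an estimated correlation. Muscle (0 and 0 of 55, 0 and 0) was called downward at adjusted p = 0.00312, and adjusted p = 0.488 with an estimated correlation. Yolk proteins (0 and 0 of 40, 2 and 1 adjusted over the list alone) were called upward at adjusted p = 5.22e-06, and adjusted p = 0.304 with an estimated correlation. Serine proteases rose (3 and 0 of 37, 3 and 0) at adjusted p = 0.00356, and adjusted p = 0.304 with an estimated correlation. Conjugation and efflux rose (3 and 0 of 135, 3 and 0) at adjusted p = 0.0346, and adjusted p = 0.304 with an estimated correlation. Ribosomal proteins rose (1 and 0 of 173, 0 and 0) at adjusted p = 2.28e-08, and adjusted p = 0.487 with an estimated correlation. The count of 425 was 796 without GA+EPA 4, 184 without GA+EPA 2, 176 without CRY 1 and 137 without CRY 2. It was 998 with DESeq2, 43 with only these groups, 211 with a 2-fold minimum and 56 with a block for the library number. With limma on FPKM 27.3% of the calls were higher in place of 46.8%.

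Against CY+EPA, the flagellate diet (CRY vs CY+EPA) raised the Niemann-Pick type C gene from 53.77 ± 9.91 to 1670 ± 383 CPM (4.96 ± 0.39, adjusted p = 8.09e-05). A secreted protein (APZ42_021660) rose from 1.59 ± 0.376 to 23.12 ± 5.54 CPM (3.86 ± 0.25, adjusted p = 1.28e-05) and NRAMP2 from 36.92 ± 3.42 to 151 ± 36.2 CPM (2.03 ± 0.19, adjusted p = 0.000309). The pancreatic lipase-related gene fell from 197.7 ± 19.6 to 60.06 ± 9.14 CPM (−1.72 ± 0.19, adjusted p = 0.00121). Of 15377 genes 49 rose and 28 fell. The sterol list rose (1 and 0 of 24, 7 and 0 adjusted over the list alone, adjusted p = 0.000106), and its call stood with an estimated correlation (adjusted p = 0.0162). Hormone signalling rose (1 and 0 of 25, 7 and 0) at adjusted p = 0.0183 (0.608 with an estimated correlation). Opsins rose (1 and 0 of 45, 1 and 1) at adjusted p = 0.0178, and adjusted p = 0.608 with an estimated correlation. Cuticle proteins (0 and 0 of 148, 0 and 0) were called upward at adjusted p = 0.0293, and adjusted p = 0.816 with an estimated correlation. Beta-oxidation fell (0 and 2 of 29, 0 and 3 adjusted over the list alone) at adjusted p = 0.00714, and adjusted p = 0.457 with an estimated correlation. Ribosomal proteins (0 and 0 of 173, 0 and 0) were called downward at adjusted p = 2.54e-06, and adjusted p = 0.816 with an estimated correlation. The count of 77 was 510 without CRY 5, 42 and 27 without CRY 1 and CRY 2, 26, 35 and 23 without CY+EPA 1, 2 and 3, and 665 without CRY 5 and CY 3. It was 449 with DESeq2, 276 with only these groups and 27 with a block for the library number.

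The log2 fold changes of GA+EPA vs GA and CRY vs CY, which share no library, correlated with r = 0.266 (jackknife standard error 0.249), which does not set it apart from 0. From means of log2 CPM it was 0.313, and up to 0.308 in size in other groupings of the GA and GA+EPA libraries. The fitted r over 15377 genes, which are not independent replicates, was 0.049 without CY 3, 0.124 without GA+EPA 2 and 0.151 without CRY 2. Those of CY+EPA vs CY and CRY vs GA had r = 0.028 (standard error 0.165, −0.124 to 0.075 with a library omitted), and the EPA effects on the 2 foods r = 0.009 (0.264, −0.212 to 0.147). Neither was set apart from 0. Genes called in both CRY vs GA and CRY vs CY were 53 higher and 4 lower, with 9 opposite. Independent lists would share 4.42 and 1.28, and simulated unchanged groups, where hardly any gene is called at all, shared 0 and 0. What the shared CRY libraries add to such overlaps was therefore not measured. The covariance of these fold changes was 0.131 (r = 0.25), against 0.088 (r = 0.5) in simulations with the same CRY libraries.

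With GA as the shared reference, GA+EPA vs GA and CRY vs GA had 260 higher and 296 lower genes in common (27.7 and 24.6 for independent lists). They had 12 in opposite directions, among them the acyl-CoA dehydrogenase APZ42_017127. GA+EPA vs GA and CY vs GA shared 195 higher and 287 lower genes (31 and 34.7), with 28 opposite. CY vs GA and CRY vs GA shared 381 higher and 510 lower (38.9 and 45), with 10 opposite. The fold changes of these comparisons share the GA libraries, which in simulations gave correlations of 0.5, 0.5 and 0.49 by themselves. The measured values were 0.62, 0.46 and 0.83, with covariances of 0.557, 0.417 and 0.741 against 0.087 simulated. Part of these overlaps may come from the shared GA libraries. The food comparisons CY vs GA and CY+EPA vs GA+EPA, which share no library, had 325 higher and 361 lower genes in common (58.3 and 93.5), with 10 opposite. Both also compare the same ranges of library numbers, so a difference between these ranges could give such an overlap too. With a block for the library number they had 47 and 2 calls.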

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

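The tests of GA 1 against GA 2 and GA 3 in genes called in GA+EPA vs GA, the test of a shared EPA response in those called lower, and the tests on the elongase, desaturase and collagen genes, and on CRY 5 as a CY sample were chosen after the results were seen. The others were written before.

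The interaction test singled out 90 genes whose response to EPA differed between the foods, because it compares the EPA effects on CY and GA directly. Trypsin-7 APZ42_020188 had a difference of 1.57 (adjusted p = 0.0109, −0.87 on the alga and 0.70 on the cyanobacterium), lost only without CY 2. Zinc carboxypeptidase A1 (APZ42_000512) had −1.77 (adjusted p = 0.0256, 1.77 and 0.00), trypsin-7 APZ42_013587 1.10 (0.0256, −1.10 and 0.00) and lysosomal alpha-glucosidase (APZ42_021394) −1.11 (0.0283, 1.18 and 0.06). Elongase 1 (APZ42_011361) had 4.23 (0.032, −3.70 and 0.53), a carboxypeptidase (APZ42_012742) 0.93 (0.0327, −0.81 and 0.12) and carbonic anhydrase 14 (APZ42_022519) −4.72 (0.0352, 4.15 and −0.57). A trypsin (APZ42_031107) had −1.70 (0.0372, 1.60 and −0.10), neutral alpha-glucosidase AB (APZ42_019360) −1.74 (0.0373, 0.73 and −1.01) and a mannanase (APZ42_011768) 2.18 (0.0427, −2.22 and −0.04). Aquaporin-2 (APZ42_033739) had −6.86 (0.043, 6.26 and −0.60), a juvenile hormone binding protein (APZ42_028755) −1.35 (0.0459, 1.49 and 0.14) and cytochrome P450 4d21 (APZ42_019407) −1.38 (0.0459, 1.36 and −0.02). Without CY 2 only 2 genes were called, both positive, so every gene here with a negative difference lost its call. Without any other library of CY or CY+EPA 7 to 12 genes were called, 2 or 3 of them negative.

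For the interaction 5 of 100 groupings of the libraries gave at least as many calls as the labels (highest 204), so chance is not excluded. For the averaged EPA effect 2 of 100 did (171 with the labels, highest 204). The combinations include the CY sides in either order, so the same 204 enters both tests. In the given order the next highest averaged count was 160. With GA as labelled and CY regrouped the interaction count ran from 13 to 204 over 18 groupings, and with GA regrouped it reached at most 3, so both counts rest on the difference of GA+EPA from GA. For single comparisons only 10 groupings exist, which cannot give a share under 0.1. In 1 of 10, the labels themselves, the count was reached in GA+EPA vs GA (1122, next 87), CY vs GA (1807, next 13), CY+EPA vs GA+EPA (2550, next 0), CRY vs GA (1432, next 0), CRY vs CY (121, next 4), CRY vs GA+EPA (425, next 5) and CRY vs CY+EPA (77, next 0). In CY+EPA vs CY it was 10 of 10, all at 0.

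The first pattern weighed is the set of genes called in GA+EPA vs GA. If GA 2 and GA 3 carried it and GA 1 did not, then among genes called without GA 1 the median difference from GA 1 would be a small part of that from GA 2 and GA 3. The ratio was 0.706 (0.647 to 0.781) over 478 higher genes, which argues against that as their whole cause, and 0.462 (0.413 to 0.538) over 553 lower genes, which leaves it open for them. A shared EPA response would move the same genes on the cyanobacterium. Medians there were −0.076 (−0.097 to −0.06, against −1.642 on the alga) and −0.018 (−0.038 to 0.003, against 1.108). Ranges over genes, not libraries, leave it open. For 17 elongase, desaturase and collagen genes the ratio was 0.308 (0.129 to 0.6, −1.056 against −3.429), so a molt-linked or other programme of GA 2 and GA 3 stays open, and the stage of the animals may differ between pools, which was not tested.

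The second pattern is CRY 5, which lay apart from CRY 1 and CRY 2. A CY sample under a CRY label would lie at 0 between CY (0) and CRY (1), but CRY 5 lay at 0.668 (0.537 to 0.777, 45 genes) and CY 3 at −0.052, which argues against it. RNA of CY 3 mixed into CRY 5 would give the same share from genes higher in CRY and genes higher in CY. The shares were 0.492 (0.21 to 0.841, 27 genes) and 0.246 (0.143 to 0.365, 18 genes), a difference of 0.246 within wide ranges, so mixing could account for it on weak evidence. A CY+EPA source or a biological cause was not tested.

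The third pattern is the difference between CY and GA, which coincides with the library number. If the number range drove it, CRY 2 would differ from CRY 1 as GA does from CY, with a slope near 1, and the slope was −0.038 (0.053 against CRY 5) over 1807 genes. A single library of the higher range in CRY and genes picked for the CY vs GA difference keep this from deciding, so food and number range cannot be told apart by these data.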

How the results depend on the processing

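With 3 libraries per diet, only 6% to 19.4% of 1.5-fold and 37.3% to 50.7% of 2-fold simulated changes were found. Diet and library number are joined for GA against CY, opsins, globins, ferritins and elongases lie in clusters whose reads may be shared, and the pool size is given in 2 ways by the labels. List results below are those of called lists, with uncalled lists given as counts. Names of genes in the text were picked by rule and then narrowed after the values were seen.

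With single libraries left out in turn (a leave-one-out for each replicate), the counts of genes called ran from 598 to 1091 in GA+EPA vs GA, 11 to 326 in the averaged EPA effect, 2 to 211 in the interaction and 750 to 1739 in CY vs GA. They ran from 612 to 3245 in CY+EPA vs GA+EPA, 608 to 1962 in CRY vs GA, 49 to 561 in CRY vs CY, 137 to 796 in CRY vs GA+EPA and 23 to 510 in CRY vs CY+EPA. Of 72 counts 22 stayed within 1.5 times, 6 of them in CY+EPA vs CY, where 0 throughout says nothing of stability. List calls kept their direction and their side of the threshold in 386 of the tests, ended in 112 and turned direction in 6, while 52 of 1584 tests of other lists became called. Lowest and highest adjusted p over the omissions were 0.0104 to 0.0601 (sterols), 0.000126 to 0.0779 (carbohydrate digestion), 1.21e-07 to 0.913 (cuticle), 0.00518 to 0.0925 (opsins), 1.89e-06 to 0.111 (respiratory chain) and 0.00531 to 0.101 (neurotransmission) in GA+EPA vs GA. It was 0.0173 to 0.0952 (sterols), 0.000979 to 0.149 (carbohydrate digestion), 2.58e-06 to 0.888 (cuticle), 0.0105 to 0.101 (opsins) and 0.00599 to 0.0931 (neurotransmission) in the averaged EPA effect, and 0.00208 to 0.124 (desaturases and elongases) and 9.21e-05 to 0.106 (other peptidases) in the interaction. Next came 0.000181 to 0.106 (carbohydrate digestion), 5.48e-07 to 0.928 (cuticle), 0.00384 to 0.158 (opsins) and 0.000561 to 0.589 (ribosome) in the interaction, and 0.00113 to 0.337 (lipases), 7.66e-11 to 0.0545 (cuticle) and 0.0116 to 0.0711 (chitin) in CY vs GA. Then came 7.7e-05 to 0.136 (antioxidants), 0.00129 to 0.105 (muscle) and 0.000723 to 0.187 (DNA replication) in CY vs GA, 0.00764 to 0.0875 (yolk) and 0.0229 to 0.174 (serine proteases) in CY+EPA vs GA+EPA, and 0.00904 to 0.0913 (beta-oxidation) and 0.0105 to 0.16 (hormones) in CRY vs GA. There followed 0.00685 to 0.128 (serine proteases), 0.000325 to 0.262 (other peptidases), 1.25e-06 to 0.754 (cuticle), 0.00665 to 0.118 (conjugation) and 2.19e-05 to 0.128 (ribosome) in CRY vs GA, and 0.0226 to 0.0609 (other peptidases) and 0.00226 to 0.408 (cuticle) in CRY vs CY. Further values were 0.00124 to 0.0898 (ribosome) in CRY vs CY, 0.0064 to 0.142 (conjugation) and 8.23e-05 to 0.0848 (muscle) in CRY vs GA+EPA, and 0.00263 to 0.363 (cuticle) and 0.0125 to 0.211 (opsins) in CRY vs CY+EPA. The cuticle list turned direction in GA+EPA vs GA without GA 1 (0.911) and GA+EPA 2 (0.913), in the averaged EPA effect without GA 1 (0.711) and GA+EPA 2 (0.888), and in the interaction without GA 1 (0.878) and GA+EPA 2 (0.928). The cause was not tested. For named genes 939 omissions stood and 255 ended the call, with no change of direction. Here and below uncalled CY+EPA vs CY genes count as stood.

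With camera at an estimated correlation, 3 of 72 list calls stood and 69 ended. Adjusted p was then 0.321 (sterols), 0.79 (carbohydrate digestion), 0.924 (cuticle), 0.639 (opsins), 0.79 (respiratory chain) and 0.639 (neurotransmission) in GA+EPA vs GA. Adjusted p reached 0.371 (sterols), 0.904 (carbohydrate digestion), 0.904 (cuticle), 0.706 (opsins) and 0.691 (neurotransmission) in the averaged EPA effect, and 0.781 (desaturases and elongases) and 0.835 (other peptidases) in the interaction. The value was 0.781 (carbohydrate digestion), 0.835 (cuticle), 0.781 (opsins), 0.835 (ribosome) and 0.781 (respiratory chain) in the interaction, and 0.467 (lipases) and 0.467 (yolk) in CY vs GA. Lists lost also had 0.467 (other peptidases), 0.467 (carbohydrate digestion), 0.579 (cuticle), 0.29 (chitin), 0.29 (haemoglobin and iron), 0.103 (opsins) and 0.467 (antioxidants) in CY vs GA. It was 0.467 (ribosome), 0.467 (respiratory chain), 0.579 (muscle), 0.579 (DNA replication) and 0.29 (neurotransmission) in CY vs GA, and 0.608 (yolk) and 0.581 (serine proteases) in CY+EPA vs GA+EPA. Next came 0.608 (cuticle), 0.428 (haemoglobin and iron), 0.428 (opsins), 0.482 (ribosome) and 0.619 (muscle) in CY+EPA vs GA+EPA, and 0.298 (beta-oxidation) and 0.0888 (sterols) in CRY vs GA. Then came 0.437 (hormones), 0.262 (yolk), 0.426 (serine proteases), 0.579 (other peptidases), 0.666 (cuticle), 0.114 (haemoglobin and iron) and 0.221 (opsins) in CRY vs GA. There followed 0.298 (conjugation), 0.579 (ribosome), 0.426 (respiratory chain), 0.437 (muscle) and 0.262 (neurotransmission) in CRY vs GA, and 0.679 (other peptidases) and 0.814 (cuticle) in CRY vs CY. Further values were 0.679 (ribosome) in CRY vs CY, and 0.119 (beta-oxidation), 0.304 (yolk), 0.304 (serine proteases), 0.488 (cuticle), 0.304 (opsins) and 0.304 (conjugation) in CRY vs GA+EPA. Adjusted p reached 0.487 (ribosome) and 0.488 (muscle) in CRY vs GA+EPA, and 0.457 (beta-oxidation), 0.608 (hormones), 0.816 (cuticle), 0.608 (opsins) and 0.816 (ribosome) in CRY vs CY+EPA. Every call of a COG class ended as well. No direction changed, and the cause was not tested.

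The replicate numbers in the titles did not pair the libraries. Of 22 pairs with the same number 5 had a correlation of deviations over 0.1 (from −0.283 to 0.3), with a median of 0.022 against 0.001 for other pairs. With a replicate block the counts were 324 in the averaged EPA effect, 164 in the interaction, 248 in CRY vs CY and 227 in CRY vs CY+EPA. In GA+EPA vs GA it gave 1036 calls, 63.7% of them higher in place of 51.9%. It left 52 list calls and ended 20, and 4 other lists became called. Adjusted p for those that ended was 0.0653 (sterols), 0.0578 (opsins), 0.0653 (respiratory chain) and 0.0653 (neurotransmission) in GA+EPA vs GA, and 0.0837 (sterols), 0.0634 (carbohydrate digestion) and 0.0837 (opsins) in the averaged EPA effect. The value was 0.0634 (neurotransmission) in the averaged EPA effect, 0.101 (desaturases and elongases) in the interaction, 0.0619 (lipases) and 0.0619 (DNA replication) in CY vs GA, and 0.193 (serine proteases) and 0.0777 (muscle) in CY+EPA vs GA+EPA. Lists lost also had 0.0792 (hormones), 0.184 (serine proteases), 0.244 (other peptidases) and 0.417 (cuticle) in CRY vs GA, 0.362 (serine proteases) in CRY vs GA+EPA, and 0.0581 (hormones) and 0.296 (opsins) in CRY vs CY+EPA. Of the named genes 157 stood and 42 ended, cause not tested.

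With CRY 5 and CY 3 both left out, chosen after the data were seen, the counts were 16 in the averaged EPA effect, 2257 in CRY vs GA and 665 in CRY vs CY+EPA, with 5 others within 1.5 times. It left 42 list calls and ended 17, and 4 of 173 tests of other lists became called. Adjusted p for those that ended was 0.0891 (carbohydrate digestion), 0.0891 (cuticle) and 0.0655 (neurotransmission) in the averaged EPA effect, and 0.157 (desaturases and elongases), 0.112 (other peptidases), 0.119 (carbohydrate digestion) and 0.0515 (opsins) in the interaction. It was 0.117 (lipases), 0.0596 (chitin) and 0.051 (antioxidants) in CY vs GA, and 0.0821 (hormones), 0.182 (serine proteases), 0.241 (other peptidases) and 0.792 (cuticle) in CRY vs GA. Next came 0.145 (ribosome) in CRY vs GA, and 0.0664 (hormones) and 0.217 (opsins) in CRY vs CY+EPA. Of the named genes 131 stood and 14 ended. The cause was not tested.

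With GA 2 and GA 3 both left out, also chosen afterwards, GA is 1 library and is assumed to vary like the other groups. The counts were 235 in GA+EPA vs GA, 90 in the averaged EPA effect, 395 in CY vs GA and 270 in CRY vs GA, and the interaction stayed within 1.5 times. It left 38 list calls and ended 7, and 15 of 99 tests of other lists became called. Adjusted p for those that ended was 0.0697 (neurotransmission) in GA+EPA vs GA, 0.262 (desaturases and elongases) and 0.144 (ribosome) in the interaction, 0.941 (cuticle) and 0.257 (DNA replication) in CY vs GA, and 0.1 (beta-oxidation) and 0.274 (hormones) in CRY vs GA. The cuticle list in CRY vs GA turned direction (0.1), as did 2 genes: APZ42_030894 in GA+EPA vs GA (0.186) and APZ42_020452 in CRY vs GA (0.128). Of the named gene calls 52 stood and 114 ended. The cause was not tested.

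With list members from product names only, chosen afterwards, 57 list calls stood and 14 ended. Adjusted p for those that ended was 0.0519 (carbohydrate digestion) and 0.147 (cuticle) in the averaged EPA effect, 0.0576 (cuticle) in the interaction, and 0.0529 (lipases), 0.344 (yolk) and 0.0642 (chitin) in CY vs GA. Then came 0.779 (yolk), 0.079 (serine proteases) and 0.055 (haemoglobin and iron) in CY+EPA vs GA+EPA, 0.0677 (beta-oxidation) in CRY vs GA, 0.0614 (conjugation) in CRY vs GA+EPA, and 0.062 (beta-oxidation) and 0.136 (hormones) in CRY vs CY+EPA. There followed 0.062 (cuticle) in CRY vs CY+EPA. The hormone list in CRY vs GA turned direction (0.881). The cause was not tested.

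With only the groups compared fitted, counts were 0 in GA+EPA vs GA, 93 in the averaged EPA effect and 35 in the interaction. They were 1068 in CY vs GA, 1138 in CY+EPA vs GA+EPA, 355 in CRY vs GA and 43 in CRY vs GA+EPA. All of these fell and involve GA or GA+EPA, whose libraries lay furthest apart. On fewer libraries too, CRY vs CY+EPA rose from 77 to 276. Of named genes 88 stood and 102 ended. With the DESeq2 Wald test they were 1792 in GA+EPA vs GA, 1 in CY+EPA vs CY, 801 in the averaged EPA effect, 607 in the interaction, 410 in CRY vs CY, 998 in CRY vs GA+EPA and 449 in CRY vs CY+EPA, and 194 named gene calls stood and 5 ended. With at least 2-fold changes they were 703 in GA+EPA vs GA, 49 in the averaged EPA effect, 725 in CY vs GA, 956 in CY+EPA vs GA+EPA, 673 in CRY vs GA, 72 in CRY vs CY and 211 in CRY vs GA+EPA, which removes smaller changes by construction. With limma on log2(FPKM + 1) they were 2880 in CY vs GA and 2968 in CRY vs GA, and 172 named gene calls stood and 27 ended. Those calls were 12.3% and 13.4% higher in place of 45.3% and 51%. FPKM lacks the TMM scaling, whose factors were 1.033 to 1.158 in GA and 0.929 to 0.984 in CY and CRY. Without it fold changes over GA are lower, with medians shifted by −0.152 (CY) and −0.177 (CRY). The cause was not tested for DESeq2.

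With a library number block the counts were 47 in CY vs GA, 2 in CY+EPA vs GA+EPA, 372 in CRY vs GA, 47 in CRY vs CY, 56 in CRY vs GA+EPA and 27 in CRY vs CY+EPA, and 46 named gene calls stood and 94 ended. In these comparisons the block rests on CRY 2 against CRY 1 and CRY 5 alone. For the EPA comparisons within a food the block was not run, because both groups lie in 1 number range.

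With DESeq2 size factors all 10 counts stayed within 1.5 times. Of list calls 70 stood and 2 ended (lipases in CY vs GA, 0.05, and hormones in CRY vs GA, 0.0506). Of named genes 198 stood and 1 ended. No count moved by more than 1.5 times without a count filter (187 named gene calls stood, 12 ended) or without the genes of the cuticle, chitin and collagen lists, chosen afterwards. The correlation of GA+EPA vs GA with CRY vs CY was 0.35 over genes of at least 5 CPM and 0.34 from FPKM. That of CY+EPA vs CY with CRY vs GA was −0.019 and −0.021, and that of the EPA effects on the 2 foods −0.077 and −0.081.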

Other observations

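The genes in this part were picked after the values were seen, and no further test was run on them.

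NRAMP2 (APZ42_029718) was highest on CRY (151 ± 36.2 CPM) and GA+EPA (72.56 ± 5.94), against 35.84 ± 5.43 on GA, 29.05 ± 5.58 on CY and 36.92 ± 3.42 on CY+EPA. Ferric-chelate reductase 1 (APZ42_021650) held 30.86 ± 7.24 CPM on CRY and 13.19 ± 4.51 on GA+EPA, against 7.139 ± 0.601 on GA, 6.31 ± 1.96 on CY and 8.958 ± 1.2 on CY+EPA. Ferritin 1 and ferritins APZ42_022342 and APZ42_029162 were highest on CRY too (1293, 256.8 and 97.44 CPM). Other genes of iron handling did not follow. Ferric-chelate reductase APZ42_011064 held 118.6 CPM on GA, 3.25 on GA+EPA and 5.028 on CRY, transferrin APZ42_015262 held 15.97, 8.247 and 8.406, and ferritin heavy chain APZ42_016483 held 308.2, 301.2 and 282.7. Epididymal secretory protein E1 (APZ42_015037) and its neighbour on the scaffold, the Niemann-Pick type C gene (APZ42_015058), had the same order of diets. The former held 743.7 ± 160 CPM on CY, 1082 ± 44 on CY+EPA, 1934 ± 404 on GA, 3656 ± 1160 on GA+EPA and 4225 ± 563 on CRY. The latter held 24.52 ± 5.55, 53.77 ± 9.91, 208.2 ± 73.8, 735.8 ± 322 and 1670 ± 383 CPM.

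Genes with their lowest mean on GA were also picked. Zinc carboxypeptidase A1 (APZ42_000512) held 23.1 ± 6.96 CPM on GA and 78.69 ± 5.21, 79.21 ± 11.6, 79.4 ± 4.74 and 58.25 ± 8.31 on GA+EPA, CY, CY+EPA and CRY. Leukotriene A-4 hydrolase (APZ42_022054) held 66.86 ± 28.9 CPM on GA and 193.9 ± 13.5, 193.8 ± 13.1, 199.6 ± 11 and 125.1 ± 7.92 on the others.

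On the axis with 36% of the variance GA+EPA 2 lay at 120.1, against 46.5 and 12.1 for the other GA+EPA libraries. CRY 5 lay there at −37.6, near CY+EPA (−36.4 to −41.8) and CY 3 (−46.8), and CRY 1 and CRY 2 at 11.5 and 16. Food RNA was not assessed, as the photosynthesis list matched 0 genes.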
